A study of Mus musculus with 15 samples.

How the data were processed

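Gene expression was measured in AtT20 cells, a mouse pituitary corticotroph line that makes pro-opiomelanocortin, on Affymetrix mouse expression arrays. The 15 arrays formed 5 groups of 3, which the series text describes as biological triplicates. In the NSBP1 siRNA and control siRNA groups the cells were transfected for 5 days and were split and transfected again after 2 days, per the labels' protocols. In the NSBP1WT, NSBP1SE and empty vector groups the cells were clones made by retroviral infection, and NSBP1SE is a mutant protein that does not bind nucleosomes. Whether the 3 arrays of such a group are separate clones or cultures of a single clone is not clear from the sources used here. NSBP1 is the older name of the gene listed as Hmgn5. The control siRNA's sequence is not given in the sources used here. Total RNA was extracted with TRIzol and columns, treated with DNase, and labelled from total RNA with biotin, per the labels' protocols.

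The deposited table held log2 signals for 45101 probe sets, from 2.19 to 14.8. The method by which the authors summarized and normalized the arrays is not given in the sources used here. The array medians lay between 4.97 and 5.05, and the correlation across probe sets of arrays within a group lay between 0.981 and 0.997. The values were used as deposited. The number of arrays per group limits the precision.

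Of the probe sets, 64 were array controls and were left out of the tests. Of the other 45037, the platform annotation gave 34945 a single gene symbol, 932 several and 9160 none. Among those with a single symbol, 34741 were matched to the reference by Entrez identifier and 0 symbols changed. Each gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes, of which 9010 had several probe sets. Probe sets with several symbols named no gene, so Hmgn2 was not analysed here.

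A linear model with the 5 group means was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 10 residual and 5.39 prior degrees of freedom and a median standard error of 0.107 for a log2 change. All adjusted p-values of genes come from limma's moderated statistic with the Benjamini-Hochberg adjustment over all genes, at a threshold of 0.05. Rose and fell are used only of genes past this threshold. At an unadjusted p under 0.05, unchanged genes would give a share of 0.05 of the 18193 genes. The 4 comparisons of groups were NSBP1 siRNA against control siRNA, NSBP1WT and NSBP1SE each against empty vector, and NSBP1WT against NSBP1SE, which also tests the difference between the effects of both proteins. A further contrast tested the difference between the siRNA and NSBP1WT effects.

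For gene groups, 28 lists with 761 symbols were fixed from general knowledge, of which 694 entries were measured. Each list was tested in the 4 comparisons with limma's camera at a preset correlation between genes of 0.01, adjusted over the 112 tests, and again with the correlation estimated from the data. Correlations of changes across genes are descriptions, since genes are not independent replicates. NSBP1WT and NSBP1SE share their empty vector arrays, so their overlap was set beside 100 simulations of unchanged groups.

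Apart from the genes changed in both NSBP1WT and NSBP1SE, the genes named were chosen by rule. Per comparison they were the 10 largest rises and 10 largest falls among genes past the test whose 3 arrays in each group did not overlap and whose mean level was at or above the 40th percentile (5.26). To these were added Hmgn1, Hmgn3 and Hmgn5, the corticotroph genes Pomc, Tbx19, Pcsk1, Pitx1 and Neurod1, and up to 4 members of each list past the test. The last were genes changed in opposite directions under siRNA and NSBP1WT, and the 10 genes of smallest p changed the same way in NSBP1WT against both other clone groups. Genes changed in both NSBP1WT and NSBP1SE were named in addition, outside this rule. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

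The alternatives were quantile normalization, centring each array on its median, a filter at the median level, the mean of a gene's probe sets, every probe set on its own, an intensity trend, array weights, a replicate block, fits on the compared groups alone, stricter thresholds and leaving out each array in turn. Added after seeing the data were the 3′ to 5′ difference of the actin control as a covariate, the 18S ribosomal RNA signal as a covariate, fits with replicate 1 as the sole NSBP1SE array, fits on the 9 clone arrays, and array weights estimated gene by gene. The fit was tested on simulated data over 18193 genes. For NSBP1 siRNA against control siRNA it recovered 55.2% of genes changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 100% of those changed by 2. The corresponding shares were 64.2%, 94.0% and 100% for NSBP1WT against empty vector, 56.7%, 98.5% and 100% for NSBP1SE against empty vector, and 58.2%, 97.0% and 100% for NSBP1WT against NSBP1SE. In the same order, 10, 16, 7 and 8 of the 178, 188, 177 and 178 calls were false. Both simulated list shifts were recovered, with 0 false calls in the other 110 list tests. The simulated genes varied independently of each other, so this does not test the list calls where genes of a list are correlated. Each simulated gene also had the same spread in all 5 groups. The shares recovered and the false calls therefore need not hold where a group varies more than the others, as NSBP1 siRNA did. The array control probe sets were used to describe the arrays. Probe sets with several symbols or none were left out of the gene tests, and further probe sets of a gene entered only the alternatives and the checks of named genes.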

Results

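Expression was profiled in AtT20 corticotroph cells in which NSBP1, a nucleosome-binding protein of the HMGN family encoded by Hmgn5, was either lowered by siRNA or introduced with a retrovirus. HMGN proteins bind nucleosomes and loosen compact chromatin, so the comparisons ask which genes follow the amount of NSBP1 and whether nucleosome binding is needed. There were 3 arrays each for NSBP1 siRNA, control siRNA, NSBP1WT, the non-binding mutant NSBP1SE and empty vector. Changes are log2 values ± standard error. Each gene given as one of the largest rises or falls had all 3 arrays of 1 group above all 3 of the other.

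Hmgn5 itself was strongly reduced by its siRNA. Its signal was 5.98 ± 0.40 (SD, n = 3) with NSBP1 siRNA and 9.48 ± 0.11 (SD, n = 3) with control siRNA, a change of -3.50 ± 0.15 (limma adjusted p = 1.2e-09). This left 8.84% of the control signal, and the 3 arrays read 5.53, 6.11 and 6.31. The single probe set of the gene showed no rise in the arrays labelled NSBP1WT or NSBP1SE. It read 9.38 ± 0.12 (SD, n = 3) in NSBP1WT, 9.89 ± 0.08 (SD, n = 3) in NSBP1SE and 9.90 ± 0.08 (SD, n = 3) in empty vector. Hmgn5 fell in NSBP1WT (-0.52 ± 0.15, limma adjusted p = 0.0293) and did not change in NSBP1SE (-0.003, limma adjusted p = 0.999). Whether this probe set detects the introduced constructs is not known from the sources used here, so it does not check the overexpression. The fall in NSBP1WT no longer passed without NSBP1WT replicate 2 (-0.47) or 3 (-0.50) or without empty vector replicate 1 (-0.49), 2 (-0.49) or 3 (-0.56). The plot of Hmgn5 per array shows these values.

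**Figure D1:**
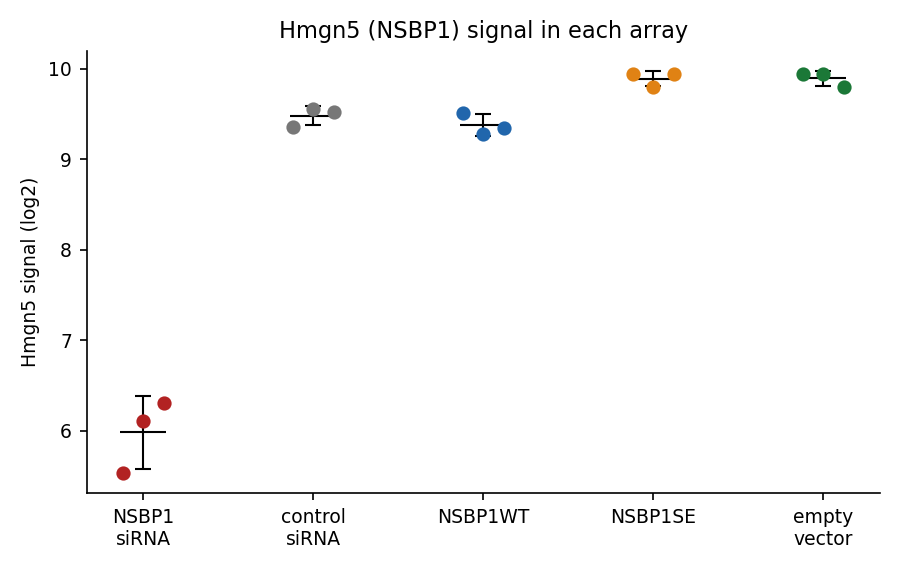
Hmgn5 signal (log2) in each of the 15 arrays by group; points are arrays, and bars are the mean and SD of 3 arrays. The NSBP1 siRNA arrays lie between 5.53 and 6.31, below all other arrays.

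With NSBP1 siRNA, single genes for hormone processing and storage fell, while the hormone gene Pomc did not pass the test. The prohormone convertase gene Pcsk1, whose product cuts pro-opiomelanocortin to corticotropin, fell, as did the granule gene Chga and the granule membrane gene Ptprn. The largest rise was in Nhlh2, a neuronal helix-loop-helix factor that activates the Pcsk1 promoter in other cells. Its level was 7.48 with NSBP1 siRNA, 7.02 in empty vector, 6.45 in NSBP1WT and 7.54 in NSBP1SE, and 4.59 with control siRNA, so the size of this rise rests on the control siRNA arrays. The antigen presentation gene Tapbp and the NF-kB subunit gene Relb rose, and Derl3 and Syvn1, which act in endoplasmic reticulum quality control, fell.

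With NSBP1 siRNA, 3464 of the 18193 genes passed the test, 1356 higher and 2108 lower, and 939 of them changed at least 1.5-fold. At an unadjusted p under 0.05 there were 6329 genes. The groups did not overlap in 27.4% of genes, where chance gives 10%. Quantile normalization turned the balance of directions, with 1980 genes higher and 1623 lower, and 2773 genes passed in both fits. The filter at the median level moved it the other way, with 527 higher and 2214 lower. The count was 1912 without NSBP1 siRNA replicate 1, 2182 without replicate 2, 6531 without replicate 3 and 2062 without control siRNA replicate 3. It was 468 with the 6 siRNA arrays fitted on their own and 1668 with the actin covariate, which was chosen after the data were seen. The main fit gave each gene the same spread in all groups, but the NSBP1 siRNA arrays varied more. Their replicates 1 and 3 differed with an SD across genes of 0.435, where pairs in other groups lay between 0.147 and 0.226. Standard errors and adjusted p-values of genes under siRNA, here and below, can therefore be too small. Arrays did not overlap for 3027 of the 3464 genes, and for 2350 of the 2354 genes in NSBP1WT.

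The largest rises were Nhlh2 (2.89 ± 0.14, adjusted p = 7.8e-09), the secreted protease gene Adamts9 (1.87), Iffo2 (1.60), Tmem176a (1.38), the class II invariant chain Cd74 (1.38), the WNT antagonist Dact1 (1.28), the TGF-beta pseudoreceptor Bambi (1.24), Zg16 (1.20), the NF-kB subunit Relb (1.20) and the peptidase Mmel1 (1.19). After Hmgn5, the largest falls were the hepcidin genes Hamp2 (-1.95 ± 0.08, adjusted p = 1.2e-09) and Hamp (-1.85), the G protein regulator Rgs4 (-1.92), and the repressor complex genes Brms1l (-1.78) and Cbx6 (-1.63). Rnf157 (-1.63), Cyria (-1.57), Pcdhb9 (-1.57) and Aldh1a7 (-1.56) followed. For Adamts9, Hamp2, Rgs4, Zg16 and Cyria, no other probe set of the gene passed, so their changes rest on 1 probe set.

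Of 32 measured genes of the regulated secretory pathway, 1 rose and 10 fell, or 1 and 12 adjusted over the list alone. Chga (-0.59 ± 0.07, adjusted p = 4.9e-05), Pcsk1 (-0.59 ± 0.08, adjusted p = 1.2e-04) and Ptprn (-0.57) fell, while the syntaxin gene Stx1a rose (0.85). As a group these genes were lower (median -0.12, adjusted p = 0.00478, and adjusted p = 0.606 with an estimated correlation), a call that ended with the filter at the median level (0.0780). In the 3 bins of 10 by mean level just above the middle, all genes had median changes of -0.12, -0.15 and -0.12. The corticotroph identity genes did not move as a group (median 0.03, adjusted p = 0.571), with 4 of 26 higher and 3 lower, or 5 and 3 adjusted over the list alone. The glucocorticoid receptor gene Nr3c1 rose (0.59) and Nr4a2, which mediates the response to corticotropin-releasing hormone, fell (-0.54). Pomc, the line's hormone gene, did not pass (-0.03 ± 0.15, adjusted p = 0.914), nor did its regulators Tbx19 (-0.17), Neurod1 (0.17) and Pitx1 (0.07).

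Neuronal genes bound by the repressor REST went both ways, with 5 of 29 higher and 7 lower, or 6 and 11 adjusted over the list alone (median -0.02, or 0.06 with quantile normalization, mean 0.01, adjusted p = 0.725). The growth cone gene Gap43 rose (0.95), as did the tubulin gene Tubb3 (0.62), and the glutamate receptor gene Gria2 fell (-0.77).

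Among 27 WNT and TGF-beta targets, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone, led by Bambi (1.24, list median 0.18, adjusted p = 0.00764, and adjusted p = 0.408 with an estimated correlation). Of 9 markers of pituitary stem and folliculostellate cells 2 rose, or 3 adjusted over the list alone (median 0.28, adjusted p = 0.00978, and adjusted p = 0.408 with an estimated correlation). Their clearest member was the progenitor factor Sox9 (0.83 ± 0.11, adjusted p = 1.8e-04). Marker lists of other cell types also had medians above 0, with 0.25 for immune and endothelial cells, 0.21 for fibroblasts and 0.16 for other pituitary hormone cells, and did not pass (adjusted p = 0.0941, 0.119 and 0.0924). Among 45 genes of extracellular matrix and adhesion, 8 rose and 3 fell, or 8 and 3 adjusted over the list alone (median 0.08, adjusted p = 0.0464, and adjusted p = 0.506 with an estimated correlation). The laminin gene Lamc1 (0.71) and the cadherin gene Cdh2 (0.47) were among the rises. With quantile normalization, the WNT and TGF-beta targets (0.0779) and the matrix genes (0.202) lost their calls, as they did with the filter at the median level (0.0979 and 0.716), and the matrix genes with the actin covariate (0.0724). The matrix call also ended without NSBP1 siRNA replicate 1 (0.122), NSBP1 siRNA replicate 3 (0.0631), control siRNA replicate 1 (0.0529) or control siRNA replicate 3 (0.0959).

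Of 27 genes of the unfolded protein response, 1 rose and 9 fell, counts that were equal adjusted over the list alone (median -0.08, adjusted p = 0.0438, and adjusted p = 0.606 with an estimated correlation). The degradation gene Derl3 (-0.87 ± 0.12, adjusted p = 2.0e-04), the ubiquitin ligase gene Syvn1 (-0.56) and the chaperone gene Dnajb9 (-0.55) fell. Of 23 cholesterol synthesis genes, 7 fell, the same number adjusted over the list alone, among them Idi1 (-0.66) and the regulator Srebf1 (-0.38), with a group result of median -0.10, adjusted p = 0.0438, and adjusted p = 0.774 with an estimated correlation. Of 30 glycolysis and hypoxia genes, 3 fell, the same number adjusted over the list alone, including the kinase gene Pdk1 (-0.78) and Mxi1 (-0.46), with median -0.19, adjusted p = 0.00819, and adjusted p = 0.802 with an estimated correlation. Quantile normalization ended the calls on unfolded protein response (0.0779) and cholesterol genes (0.119), and so did the 18S covariate (0.0617 and 0.0786) and, for cholesterol, the actin covariate (0.0882). The filter at the median level ended the calls on unfolded protein response (0.571), cholesterol (0.555) and hypoxia genes (0.169). The unfolded protein response call ended without NSBP1 siRNA replicate 1 (0.0738), NSBP1 siRNA replicate 3 (0.0873), control siRNA replicate 2 (0.0521) or control siRNA replicate 3 (0.0638), the cholesterol call without NSBP1 siRNA replicate 1 (0.0991), NSBP1 siRNA replicate 2 (0.0538), NSBP1 siRNA replicate 3 (0.0521), control siRNA replicate 1 (0.135) or control siRNA replicate 2 (0.244), and the hypoxia call without NSBP1 siRNA replicate 3 (0.128) or control siRNA replicate 2 (0.423).

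Lists that did not pass as groups still held clear single changes. For antigen presentation (3 of 14 higher, 1 lower, median 0.01, or -0.01 with each array centred on its median, adjusted p = 0.432), the loading chaperone gene Tapbp (1.02 ± 0.08, adjusted p = 8.0e-07) and B2m (0.66) rose. For glucocorticoid targets (4 of 18 higher, 1 lower, adjusted p = 0.254), the NF-kB inhibitor gene Nfkbia rose (0.78). For p53 targets (3 of 25 higher, 7 lower, adjusted p = 0.770), Zmat3 (-0.75) and Tigar (-0.64) fell and Perp rose (0.68). Among chromatin modifiers and remodelers (5 of 43 higher, 4 lower, adjusted p = 0.424), the acetyltransferase gene Kat2b fell (-0.60) and the remodeler subunit gene Smarcb1 rose (0.40). The core histone list gave 1 higher and 1 lower of 9 (adjusted p = 0.853), the fall being H2bc21 (-1.21). Of 8 HMG genes, the other call besides Hmgn5 was a rise (median 0.11, mean -0.25, adjusted p = 0.818), and Hmgn1 (0.21) and Hmgn3 (-0.04) did not pass. With every probe set tested on its own, other probe sets of Hmgn1 rose by 0.29 (adjusted p = 0.0315) and 0.24 (adjusted p = 0.0429). Adjusted over the list alone these counts were equal, except for p53 targets (3 higher, 8 lower) and HMG genes (2 and 1). For the rises of Stx1a, Lamc1, Cdh2 and Smarcb1 and the falls of Tigar and Mxi1, another measured probe set of the gene did not pass.

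Cell cycle and biosynthesis lists did not pass. The adjusted p was 0.428 for S phase and DNA replication (0 higher, 4 lower of 38), 0.725 for G2 and mitosis (1 and 2 of 37), 0.820 for oxidative phosphorylation (0 and 0 of 39), 0.542 for ribosomal proteins (0 and 1 of 27) and 0.0769 for ribosome biogenesis and MYC targets (4 and 0 of 34). It was 0.459 for the interferon response (2 and 1 of 32), 0.221 for the ATF4 amino acid response (1 and 3 of 30), 0.770 for heat shock proteins (1 and 2 of 19), 0.951 for immediate early and CREB targets (7 and 5 of 34) and 0.725 for linker histones (0 and 1 of 3). Markers of other pituitary hormone cells (1 and 0 of 11, 0.0924), fibroblasts (1 and 1 of 13, 0.119) and immune and endothelial cells (2 and 1 of 12, 0.0941) did not pass either. For linker histones, core histones, heat shock proteins, HMG genes, REST targets and immediate early genes, the list's median, mean and test did not share a sign. Adjusted over the list alone these counts were equal, except for S phase (0 and 3), ribosome biogenesis (3 and 0), heat shock proteins (0 and 2), immediate early genes (8 and 6) and markers of immune and endothelial cells (5 and 1).

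The arrays labelled NSBP1WT differed from empty vector in genes that respond to low oxygen, a list that passed at the preset correlation but not with an estimated one (adjusted p = 0.606). These arrays also stood apart from all others in their actin and Thr spike controls, so the label is not the sole difference between the groups. The controls stood apart in opposite directions, with a larger 3′ to 5′ difference for actin and a smaller difference for the Thr spike. The tumour-associated carbonic anhydrase gene Car9, the mitophagy gene Bnip3, the glucose transporter gene Slc2a1 and the collagen hydroxylase gene P4ha1 rose. The respiratory chain gene Sdhd, the mitosis gene Ube2c and the ribosome assembly gene Nolc1 fell. The interferon target gene Usp18 and the glucocorticoid target gene Tat rose, and so did Pcsk1, the gene that fell under siRNA.

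Against empty vector, 2354 genes passed the test, 1314 higher and 1040 lower, and 495 of them changed at least 1.5-fold. At an unadjusted p under 0.05 there were 4661 genes, and the groups did not overlap in 38.6% of genes (10% by chance). Quantile normalization gave 3109 genes with 66.3% higher, beside 55.8% for the deposited values, and 2221 genes passed in both. The mean of a gene's probe sets turned the balance, with 1026 genes higher and 1159 lower. The count was 1421 without NSBP1WT replicate 1, 1536 without replicate 2, 1348 without empty vector replicate 1 and 1339 without empty vector replicate 2, and 3981 with the 6 arrays of both groups fitted on their own. The NSBP1WT arrays also stood apart in the actin control, with a 3′ to 5′ difference of 1.34 ± 0.30 (SD, n = 3) where the other 12 arrays lay between 0.40 and 0.82. The Gapdh control did not stand apart, with 0.09 ± 0.06 (SD, n = 3) where the other 12 arrays lay between -0.15 and 0.15. It was higher than in empty vector (-0.13 ± 0.02, SD, n = 3). With the actin difference as a covariate, chosen after the data were seen, 12 genes passed and the median standard error rose from 0.107 to 0.212.

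The largest rises were in Kdelr3 (2.29 ± 0.09, adjusted p = 4.7e-10), which returns proteins to the endoplasmic reticulum, Car9 (1.61 ± 0.23, adjusted p = 4.2e-04), the respiratory chain regulator Ndufa4l2 (1.44), the secreted chaperone Clu (1.27), the coat protein Copz2 (1.24), Bnip3 (1.21), Notch2 (1.16), Gnat2 (1.14), Mst1 (1.14) and Insig1 (1.13). Clu did not pass without NSBP1WT replicate 1 (adjusted p = 0.0514), and Insig1 did not pass without NSBP1WT replicate 1 (0.131), 2 (0.0794) or 3 (0.113) or empty vector replicate 2 (0.223) or 3 (0.0528). The largest falls were the actin-sequestering thymosin gene Tmsb4x (-1.47 ± 0.08, adjusted p = 4.1e-08), Glod5 (-1.37), the gap junction gene Gjd2 (-1.37), the sterol-binding Osbpl1a (-1.30), Lsm2 (-1.10), the neuronal membrane genes Lrrn3 (-1.09) and Slitrk1 (-1.06), Synpo2 (-1.05), the glutamate transporter gene Slc1a2 (-1.01) and Camk2d (-0.98). No other probe set of Notch2, Slc1a2 or Camk2d passed, and none of Ntn4 or Sln below. Against both empty vector and NSBP1SE, the genes of smallest p were Kdelr3, Abca13 (1.86), Myot (2.22), Tmsb4x, Etv5 (-1.06), Creb3l1 (0.90), Ntn4 (1.00), Glod5, Phf7 (0.91) and Sln (-0.97), with the change against empty vector given.

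Of 30 glycolysis and hypoxia genes, 16 rose and 0 fell, or 22 and 0 adjusted over the list alone (median 0.44, adjusted p = 9.7e-11, and adjusted p = 0.606 with an estimated correlation). Besides Car9 and Bnip3, Slc2a1 (1.07 ± 0.21) and P4ha1 (1.05 ± 0.14) rose. Oxidative phosphorylation moved the other way, with 14 of 39 genes lower and 1 higher, or 17 and 1 adjusted over the list alone (median -0.13, adjusted p = 7.7e-10, and adjusted p = 0.606 with an estimated correlation). The succinate dehydrogenase subunit gene Sdhd (-0.68) and the complex I gene Ndufb5 (-0.56) fell, and the other probe sets of Sdhd, Ndufb5 and P4ha1 did not pass.

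Of 37 genes of G2 and mitosis, 13 fell and 0 rose, or 18 and 0 adjusted over the list alone (median -0.20, adjusted p = 1.6e-12, and adjusted p = 0.408 with an estimated correlation). The ubiquitin-conjugating gene Ube2c (-0.84 ± 0.11, adjusted p = 2.0e-04), the spindle kinesin gene Kif11 (-0.57) and the kinetochore gene Nuf2 (-0.47) fell. In S phase and DNA replication, 10 of 38 genes fell and 1 rose, or 11 and 2 adjusted over the list alone (median -0.11, adjusted p = 8.5e-05, and adjusted p = 0.606 with an estimated correlation). The clamp loader gene Rfc3 (-0.78), Tk1 (-0.63) and the helicase gene Mcm2 (-0.57) were among the falls. Ribosome biogenesis and MYC targets were lower in 10 of 34 genes and higher in 1, or 11 and 1 adjusted over the list alone (median -0.14, adjusted p = 4.8e-05, and adjusted p = 0.606 with an estimated correlation), with falls of Nolc1 (-0.53) and Rrp12 (-0.48), and the actin covariate ended the list's call (0.113). Ribosomal protein genes gave 5 falls and 1 rise of 27, or 6 and 1 adjusted over the list alone (median -0.06, adjusted p = 0.00181, and adjusted p = 0.613 with an estimated correlation). Rpl11 (-0.55) and Rps19 (-0.41) fell, and the list's call ended with quantile normalization (0.0779) and with the actin covariate (0.304).

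Among 32 interferon response genes, 10 rose and 1 fell, or 13 and 1 adjusted over the list alone (median 0.17, adjusted p = 0.00377, and adjusted p = 0.408 with an estimated correlation). Usp18 (0.96) and the antiviral gene Rsad2 (0.72) rose, and the kinase gene Eif2ak2 fell (-0.48). Of 18 glucocorticoid targets, 6 rose, or 9 adjusted over the list alone (median 0.19, adjusted p = 0.00729, and adjusted p = 0.408 with an estimated correlation), led by the metallothionein gene Mt1 (1.01), the aminotransferase gene Tat (1.00 ± 0.09, adjusted p = 1.4e-05) and the kinase gene Sgk1 (0.65). In the HMG list 3 of 8 genes fell and 1 rose, the same adjusted over the list alone (median -0.14, adjusted p = 0.0466, and adjusted p = 0.613 with an estimated correlation). Hmgb3 (-0.60) fell, and Hmgn3 (0.26) passed in all 15 arrays but not without NSBP1WT replicate 1 (0.148) or 3 (0.112) or empty vector replicate 1 (0.0890), 2 (0.0981) or 3 (0.128). The HMG call ended without NSBP1WT replicate 1 (0.0824), NSBP1WT replicate 2 (0.106), empty vector replicate 1 (0.0785) or empty vector replicate 2 (0.0646) and with quantile normalization (0.103), the filter at the median level (0.213), the actin covariate (0.272) and the 18S covariate (0.0639).

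In corticotroph identity (1 of 26 higher, 3 lower, adjusted p = 0.221), the lineage factor gene Tbx19 fell (-0.34 ± 0.07, adjusted p = 0.00671), and Pomc did not pass (0.11 ± 0.15, adjusted p = 0.720), nor did Neurod1 (0.15) or Pitx1 (-0.02). Secretory pathway genes went both ways (6 of 32 higher, 4 lower, adjusted p = 0.490), with rises of Pcsk1 (0.46 ± 0.08, adjusted p = 9.6e-04) and Stx1a (0.51). So did WNT and TGF-beta targets (2 higher and 3 lower of 27, adjusted p = 0.720), where Id1 (-0.91), Id3 (-0.90) and Bambi (-0.76) fell and Tgfb3 rose (0.87). The immediate early genes Nr4a3 (0.98) and Fos (0.94) rose in a list of 6 rises and 2 falls of 34 (adjusted p = 0.0769). Unfolded protein response genes gave 8 rises and 2 falls of 27 (adjusted p = 0.187), with Canx (0.99) and Ern1 (0.62) each rising in 1 probe set and in no other. The neuronal genes Elavl4 (-0.83), Tubb3 (-0.62) and Gap43 (-0.48) fell, and the amino acid response genes Atf3 (0.71) and Trib3 (0.51) rose. The integrin genes Itgb5 (0.63) and Itga6 (0.41) rose, and the p53 targets Mdm2 (-0.44) and Ccng1 (-0.40) fell. Adjusted over the list alone, the higher and lower counts were 2 and 5 for corticotroph identity, 10 and 4 for the secretory pathway, 2 and 3 for WNT and TGF-beta targets, 8 and 2 for immediate early genes and 10 and 2 for the unfolded protein response. The higher and lower counts of REST-bound neuronal genes were 2 and 7 of 29 (3 and 8 adjusted over the list alone, list adjusted p = 0.119), of the ATF4 amino acid response 6 and 6 of 30 (6 and 7, 0.424), of matrix and adhesion 6 and 0 of 45 (the same adjusted over the list alone, 0.364) and of p53 targets 2 and 3 of 25 (again the same, 0.503). For WNT and TGF-beta targets, REST-bound genes, p53 targets and the ATF4 response, the median and the test had different signs, or the median and the mean did. Other probe sets of Mt1, Stx1a, Nr4a3 and Mcm2 did not pass.

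**Figure D2:**
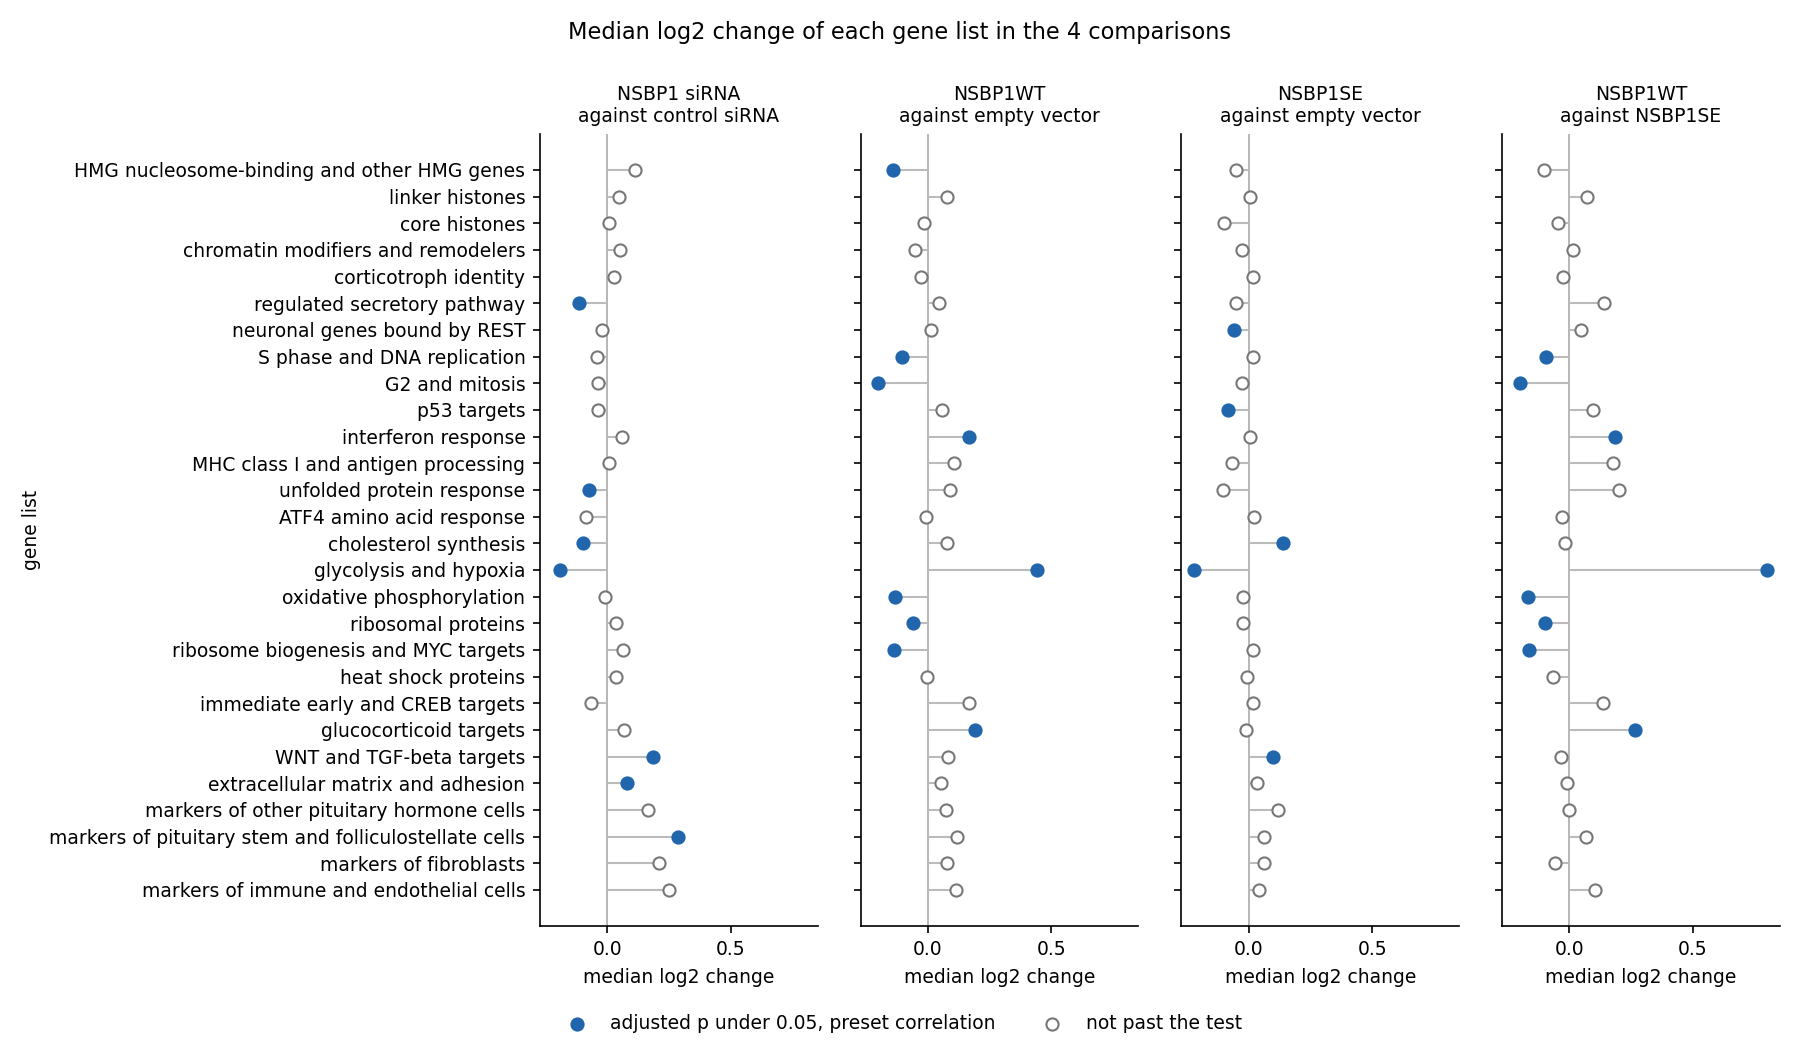
Median log2 change of the measured members of each of the 28 gene lists (horizontal axis) in each of the 4 comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation, open points did not. Glycolysis and hypoxia has the largest median in NSBP1WT against empty vector (0.44) and against NSBP1SE (0.80). With an estimated correlation 0 of the filled points passed.

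The arrays of the non-binding mutant differed from empty vector in few genes. The rises, led by the ribosomal protein gene Rpl27a and the sterol sensor gene Insig1, had a median of 1.09 in replicates 2 and 3, where the ribosomal RNA signal was high, and of 0.59 in replicate 1. There that signal lay within the range of the other groups but above every empty vector array. The falls, which were smaller, included the cytoskeletal linker gene Tln2, the guidance gene Sema5a and the growth factor gene Bmp7.

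Between NSBP1SE and empty vector 45 genes passed the test, 20 higher and 25 lower, and 1410 genes did at an unadjusted p under 0.05. The groups did not overlap in 20.1% of genes, where chance gives 10%. The count was 20 without empty vector replicate 1, 1 without empty vector replicate 2 or 3, 101 without NSBP1SE replicate 1 (81 higher, 20 lower) and 1 without NSBP1SE replicate 2 or 3. Of the genes named below, Tln2 alone (-0.61 ± 0.07, adjusted p = 0.00308) passed whichever array was left out. Rpl27a did not pass without empty vector replicate 1 (adjusted p = 0.0744), 2 (0.248) or 3 (0.0954) or without NSBP1SE replicate 2 (0.215) or 3 (0.252), nor with quantile normalization. The 18S control signal was 6.58, 9.60 and 9.82 in NSBP1SE replicates 1, 2 and 3, and lay between 5.36 and 7.21 in the 13 arrays other than replicates 2 and 3. With this signal as a covariate, chosen after the data were seen, 0 genes passed in limma. At an unadjusted p under 0.05 there were 318, a smaller share of the 18193 genes than the 0.05 that unchanged genes give. With replicate 1 as the sole NSBP1SE array, also chosen after the data were seen, the 20 rises had a median of 0.59. Quantile normalization left 23 genes, the mean of a gene's probe sets 18 and a replicate block 6, while 78 passed with the filter at the median level and 112 with an intensity trend (58 higher, 54 lower). Array weights gave 449 genes. Of the further fits chosen after the data were seen, the 9 clone arrays alone gave 190 (60 higher, 130 lower) and gene-by-gene weights 355 (115 higher, 240 lower).

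The largest rises were Rpl27a (3.21 ± 0.57, adjusted p = 0.0369), Insig1 (2.18 ± 0.35, adjusted p = 0.0261), Ptcd1 (2.01), the retention receptor gene Kdelr2 (2.00), Arglu1 (1.88), Myef2 (1.18), Abhd2 (1.09), the chaperone gene Canx (1.02), the ribosomal RNA transcription factor gene Rrn3 (0.98) and Klhl9 (0.91). Rpl27a exceeded the empty vector mean by 1.58 in replicate 1 and by 4.05 and 4.02 in replicates 2 and 3. For 19 of the 20 genes the rise was larger in replicates 2 and 3 than in replicate 1. The other 28 probe sets of 16 of these genes had a median change of -0.08, and 0 of them passed. The largest falls were Ttn (-1.17), Sema5a (-0.97), the ephrin gene Efna1 (-0.71), Bmp7 (-0.71), the kinase gene Pak3 (-0.70), the nuclear RNA Neat1 (-0.68), Perp (-0.67), Rsrp1 (-0.62), Tln2 and Spats2l (-0.58). The linker histone gene H1f2 (-0.49) and the neurofilament gene Nefl (-0.45) also fell. For Tln2, Ttn, Sema5a, Efna1, Pak3, Neat1, Rsrp1, Spats2l, H1f2 and Nefl, the gene's other probe sets did not pass. The plot of Rpl27a against 18S shows that rise in each array.

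As a group, the glycolysis and hypoxia genes were lower in NSBP1SE (median -0.22, adjusted p = 2.9e-10, and adjusted p = 0.606 with an estimated correlation). Of the 30 measured, 0 passed alone over all genes and 2 fell adjusted over the list alone. Cholesterol synthesis genes were higher as a group (median 0.14, adjusted p = 4.8e-05, and adjusted p = 0.606 with an estimated correlation), with 1 of 23 past the test, Insig1, or 2 adjusted over the list alone. WNT and TGF-beta targets were higher (median 0.10, adjusted p = 0.0149, and adjusted p = 0.408 with an estimated correlation), with 0 of 27 past the test and 1 adjusted over the list alone, and this call ended with quantile normalization (0.0660), the filter at the median level (0.0780), the 18S covariate (0.426) and replicate 1 as the sole NSBP1SE array (0.0862). REST-bound neuronal genes (median -0.06, adjusted p = 0.01, and adjusted p = 0.606 with an estimated correlation) and p53 targets (median -0.09, adjusted p = 0.0159, and adjusted p = 0.606 with an estimated correlation) were lower, each with 1 fall, Nefl of 29 and Perp of 25, the same adjusted over the list alone. The REST call ended without empty vector replicate 2 (0.0547), with the filter at the median level (0.169) and with the 18S covariate (0.107). The p53 call ended with the same filter (0.272), with the 18S covariate (0.116) and with replicate 1 as the sole NSBP1SE array (0.0612). Of 27 unfolded protein response genes 2 rose, Canx and Hyou1 (0.81), the same number adjusted over the list alone. The list's test pointed lower and did not pass (median -0.10, 6 of 27 changes above 0, list adjusted p = 0.0814). Hmgn1 (0.04), Hmgn3 (-0.15), Pomc (-0.01), Pcsk1 (0.01), Tbx19 (0.01), Neurod1 (0.02) and Pitx1 (-0.03) did not pass.

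**Figure D3:**
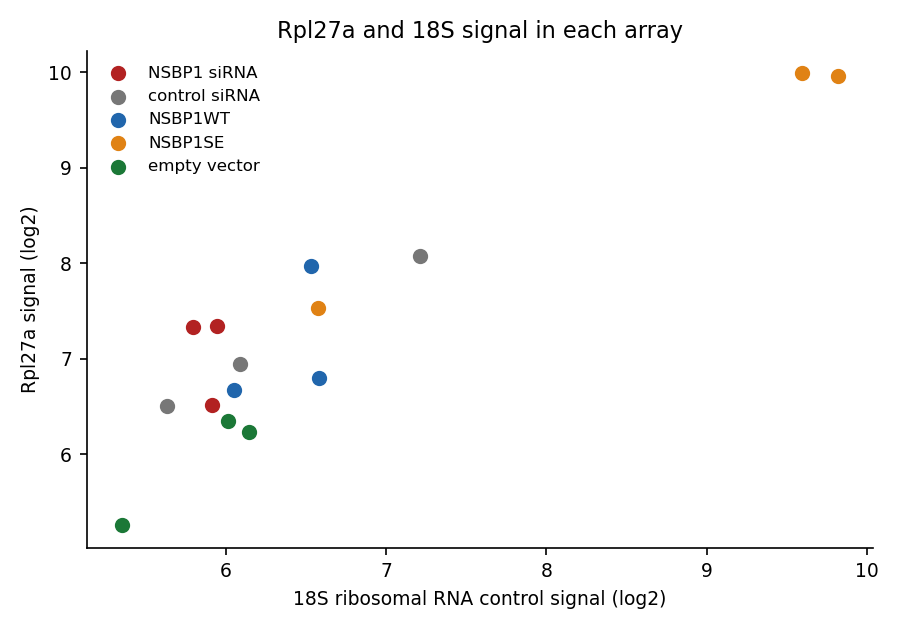
Rpl27a signal (log2, vertical axis) and 18S ribosomal RNA control signal (log2, horizontal axis) in each of the 15 arrays, coloured by group. NSBP1SE replicates 2 and 3, at 18S signals of 9.60 and 9.82, lie apart from the other 13 arrays.

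Compared directly, the NSBP1WT and NSBP1SE arrays differed in 8 of the 9 gene lists that set NSBP1WT apart from empty vector, and with an estimated correlation 0 of these lists passed (lowest adjusted p = 0.408). The hypoxia genes had the largest median. The stress gene Ndrg1 and the transcriptional repressor gene Bhlhe40, both induced by low oxygen, joined Car9 and Ndufa4l2 among the largest rises, and the inhibitor-of-differentiation gene Id1 was among the largest falls. This comparison tests the difference between both effects, because both were set against the same empty vector arrays. If each group came from a single clone, a difference between clones could not be told apart from an effect of the protein.

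In NSBP1WT against NSBP1SE 2988 genes passed, 1908 higher and 1080 lower, 698 of them changed at least 1.5-fold, and 5194 did at an unadjusted p under 0.05. The groups did not overlap in 38.1% of genes, where chance gives 10%. The count was 1826 without NSBP1WT replicate 1 and 1944 without NSBP1SE replicate 2. Of the alternatives chosen after the data were seen, the 18S covariate left 809 genes, replicate 1 as the sole NSBP1SE array 549, and the actin covariate 56.

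The largest rises were Ndufa4l2 (2.22 ± 0.22, adjusted p = 2.3e-05), Car9 (2.19 ± 0.23, adjusted p = 3.9e-05), Kdelr3 (2.12), Bhlhe40 (1.75), Clu (1.68), Kbtbd11 (1.61), Bnip3 (1.53), Ndrg1 (adjusted p = 2.5e-04), Zbtb4 (1.49) and P4ha1 (1.43). The largest falls were Glod5 (-1.57 ± 0.12, adjusted p = 3.3e-06), Gjd2 (-1.33), Tmsb4x (-1.21), Id1 (-1.20), Osbpl1a (-1.12), Nhlh2 (-1.09), Lsm2 (-1.09), the mitochondrially encoded ND5 (-1.04), Zfp942 (-1.01) and Rufy3 (-0.99). No other probe set of Zfp942 passed, and none of Ntn4 or Sln below. Of the genes lowest in p against both groups, Myot rose by 2.49, Abca13 by 2.17, Ntn4 by 1.13, Creb3l1 by 0.98 and Phf7 by 0.83, while Etv5 (-1.07) and Sln (-0.82) fell.

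Of 30 glycolysis and hypoxia genes 24 rose and 0 fell, or 25 and 0 adjusted over the list alone (median 0.80, adjusted p = 3.5e-17, and adjusted p = 0.480 with an estimated correlation). Glucocorticoid targets rose in 7 of 18 genes, or 9 adjusted over the list alone (median 0.27, adjusted p = 3.2e-04, and adjusted p = 0.408 with an estimated correlation), among them Tat (0.90), Mt1 (0.82) and the stress gene Ddit4 (0.77). Interferon response genes gave 7 rises and 1 fall of 32, or 10 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.00819, and adjusted p = 0.480 with an estimated correlation), with Usp18 at 0.93 and Rsad2 at 0.80, and the filter at the median level ended this call (0.0522). In G2 and mitosis 13 of 37 genes fell and 0 rose, or 16 and 0 adjusted over the list alone (median -0.20, adjusted p = 2.9e-10, and adjusted p = 0.480 with an estimated correlation), including Ube2c (-0.91) and the kinase gene Aurka (-0.51). S phase genes fell in 12 of 38, the same adjusted over the list alone (median -0.09, adjusted p = 5.4e-05, and adjusted p = 0.606 with an estimated correlation), with Rfc3 at -0.98 and Tk1 at -0.70. Oxidative phosphorylation gave 12 falls and 2 rises of 39, or 14 and 2 adjusted over the list alone (median -0.17, adjusted p = 7.1e-07, and adjusted p = 0.606 with an estimated correlation), with Sdhb at -0.53. Ribosome biogenesis and MYC targets gave 9 falls and 2 rises of 34, or 12 and 2 adjusted over the list alone (median -0.16, adjusted p = 1.9e-04, and adjusted p = 0.606 with an estimated correlation), with Nolc1 at -0.52, and the actin covariate ended this call (0.0724). Ribosomal protein genes gave 6 falls and 2 rises of 27, or 7 and 2 adjusted over the list alone (median -0.10, adjusted p = 0.00978, and adjusted p = 0.677 with an estimated correlation), and quantile normalization (0.175) and the actin covariate (0.357) ended that call.

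Outside these groups, Tbx19 was lower (-0.36 ± 0.07, adjusted p = 0.00390) and Pcsk1 higher (0.46 ± 0.08, adjusted p = 8.0e-04) in NSBP1WT than in NSBP1SE, and Pomc did not differ (0.12 ± 0.15, adjusted p = 0.681). Hmgn3 was higher (0.42). The histone chaperone gene Supt16 (-0.78) and the repressor complex gene Mbd3 (-0.67) were lower and the remodeler gene Chd3 higher (0.57), in a chromatin list with 5 rises and 6 falls of 43, or 6 and 6 adjusted over the list alone (adjusted p = 0.574). Unfolded protein response genes rose in 11 of 27 and fell in 2, or 11 and 4 adjusted over the list alone (adjusted p = 0.0579), with Edem1 at 0.70. Other probe sets of Hmgn3, Edem1, Aurka, Mt1 and Rsad2 did not pass. Hmgn5 was lower in NSBP1WT (-0.51 ± 0.15, adjusted p = 0.0251), a call that ended without NSBP1WT replicate 2 (0.0912) or 3 (0.0716) or NSBP1SE replicate 1 (0.0778) or 3 (0.0773).

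**Figure D4:**
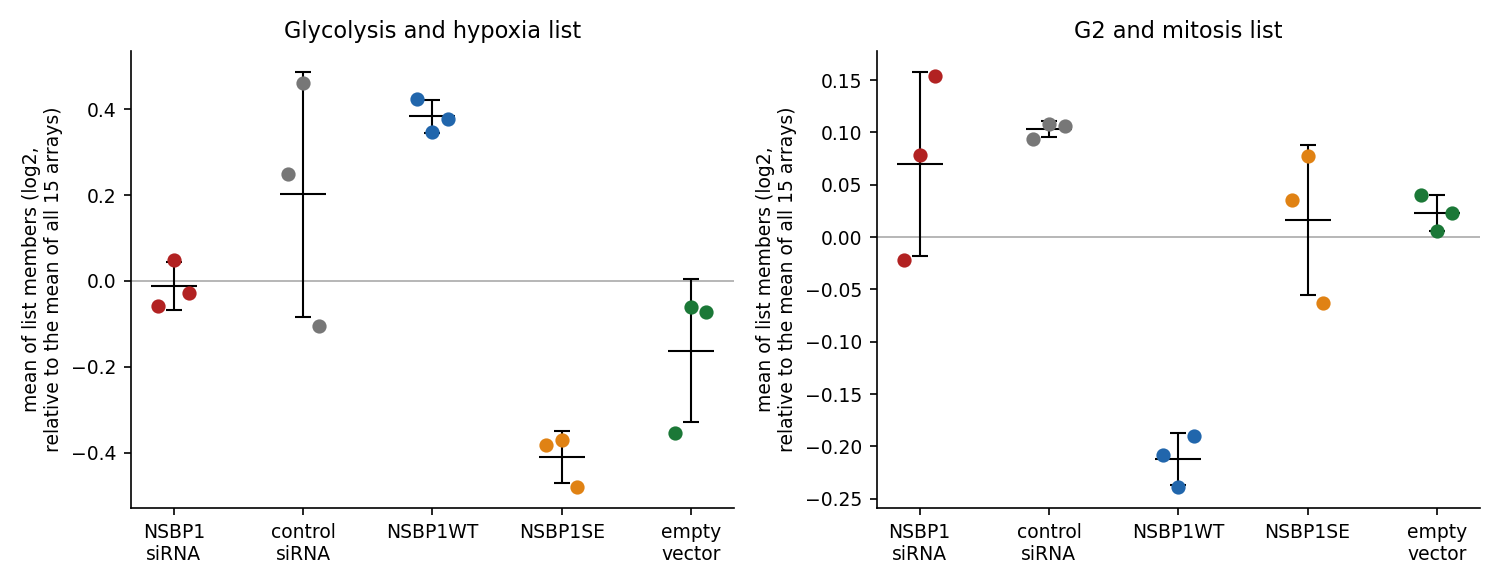
Mean of the glycolysis and hypoxia genes (left) and of the G2 and mitosis genes (right) in each array, log2 relative to the mean of all 15 arrays; points are arrays, and bars are the mean and SD of 3 arrays. The NSBP1WT arrays lie between 0.35 and 0.42 for hypoxia, where the control siRNA arrays spread from -0.11 to 0.46, and between -0.24 and -0.19 for mitosis.

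If a gene follows the amount of NSBP1, lowering and raising the protein should move it in opposite directions, and the siRNA and NSBP1WT comparisons share no arrays. A raised amount of NSBP1 was not shown in the NSBP1WT arrays, where the Hmgn5 signal was lower than in empty vector (-0.52, adjusted p = 0.0293). The Thr spike and actin controls of these arrays also stood apart. Opposite changes therefore do not by themselves show that a gene follows the amount. Pcsk1 fell with siRNA and rose in NSBP1WT. The endoplasmic reticulum stress factor gene Creb3l1, the amino acid transporter gene Slc38a3 and the myosin gene Myo1e did the same. Tmsb4x, Bambi and the neuronal factor gene Sox11 did the reverse.

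Of the genes past both tests, 399 went in opposite directions and 176 in the same direction, where n1 × n2 / N, the overlap of independent lists, gives 230 and 218. Genes lower with siRNA and higher in NSBP1WT numbered 335, where 152 were expected. The reverse pattern held 64 genes (77.5 expected), while 64 genes rose in both (97.9 expected) and 112 fell in both (121 expected). Both effects depended on expression level, with medians of -0.12 under siRNA and 0.09 in NSBP1WT in the bin just above the middle of 10. Expected within these bins, a comparison chosen after the data were seen, were 212 genes lower then higher, 46.8 higher then lower, 83.5 higher in both and 186 lower in both. Quantile normalization moved the genes changed in the same direction from 176 to 294, and the filter at the median level moved them to 268. Across all genes the effects were nearly unrelated (Pearson r = -0.0298, Spearman rho = -0.0146, across genes). The lower-then-higher genes were led by Creb3l1 (-0.75 with siRNA, 0.90 in NSBP1WT), Slc38a3 (-0.73 with siRNA, 0.84 in NSBP1WT), Aox4 (-0.75 with siRNA, 0.89 in NSBP1WT), Gsdma (-0.83 with siRNA, 0.90 in NSBP1WT) and Myo1e (-0.95 and 0.69). The higher-then-lower genes were Tmsb4x (0.90 and -1.47), Sln (0.64 and -0.97), Bambi (1.24 and -0.76), Rufy3 (0.64 and -0.85) and Sox11 (0.74 and -0.88). With siRNA, other probe sets of Rufy3 passed in both directions, and those of Slc38a3, Gsdma, Myo1e and Sln did not pass.

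The difference between the siRNA and NSBP1WT effects passed for 3078 genes, 943 with a larger value under siRNA and 2135 with a larger value in NSBP1WT, and for 5647 at an unadjusted p under 0.05. That count was 5484 without NSBP1 siRNA replicate 3. The number of opposite changes was 255 without NSBP1 siRNA replicate 2, 767 without NSBP1 siRNA replicate 3, 234 without NSBP1WT replicate 1, 253 without NSBP1WT replicate 2, 195 without empty vector replicate 1 and 220 without empty vector replicate 2. The number of genes changed in the same direction was 113 without NSBP1 siRNA replicate 2, 410 without NSBP1 siRNA replicate 3, 111 without control siRNA replicate 3, 90 without NSBP1WT replicate 2 and 115 without NSBP1WT replicate 3. It was 97, 83 and 106 without empty vector replicates 1, 2 and 3. The correlation was 0.0115 without NSBP1WT replicate 1 and 0.0133 without empty vector replicate 1.

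**Figure D5:**
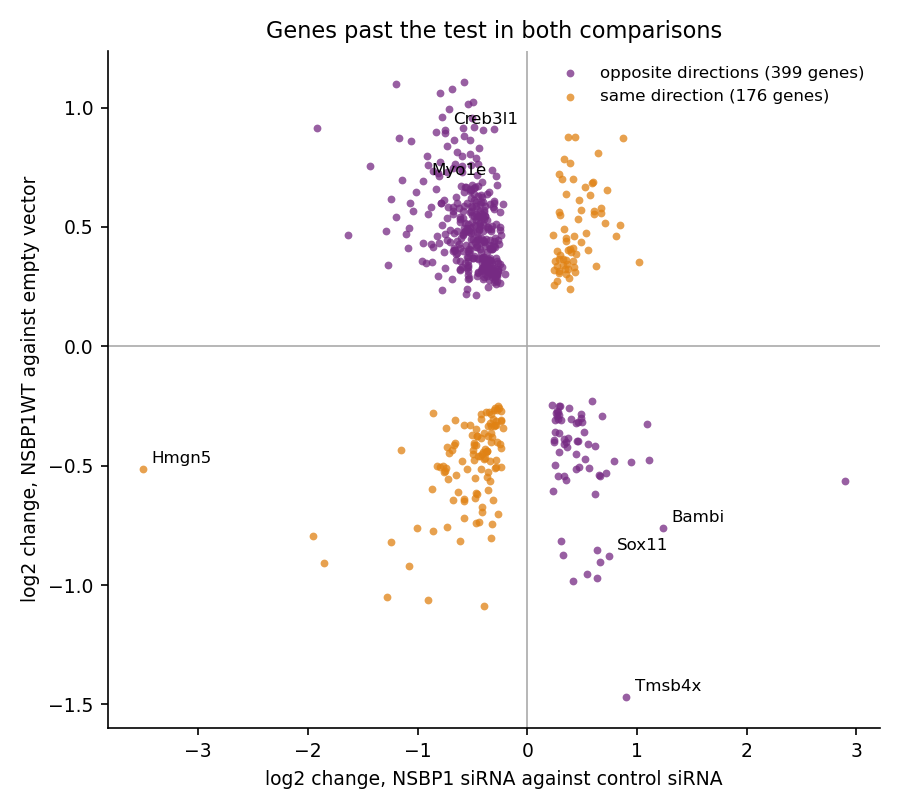
Log2 change under NSBP1 siRNA (horizontal axis) and in NSBP1WT (vertical axis) of the genes past the test in both comparisons; each point is a gene. The upper left quadrant, lower with siRNA and higher in NSBP1WT, holds 335 of the 399 genes with opposite changes.

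Some genes changed alike in both clone groups relative to empty vector, among them the neuronal transporter gene Slc1a2, the teneurin gene Tenm3 and the matrix protease gene Mmp16, which fell, and the cell cycle inhibitor gene Cdkn1b, which rose. Both proteins were set against the same 3 empty vector arrays, and the simulation of unchanged groups gave a correlation of 0.5 (at most 0.521). Unchanged groups hardly give any calls, so that simulation sets no value for the number of shared calls.

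Of the genes past both tests, 15 changed in the same direction, 7 higher and 8 lower, where n1 × n2 / N, which leaves out the shared arrays, gives 1.44 and 1.43. The rises, in NSBP1WT and NSBP1SE, were Abhd2 (0.58 and 1.09), Alkbh5 (0.64 and 0.73), Canx (0.99 and 1.02), Cdkn1b (0.45 and 0.66), Dcaf6 (0.71 and 0.74), Dpysl2 (0.60 and 0.85) and Insig1 (1.13 and 2.18). The falls were Aox3 (-0.57 and -0.88), Mmp16 (-0.82 and -0.43), Purg (-0.39 and -0.52), Sema5a (-0.55 and -0.97), Slc1a2 (-1.01 and -0.51), Stbd1 (-0.55 and -0.44), Tenm3 (-0.54 and -0.56) and Tln2 (-0.34 and -0.61). By definition all 7 rises are among the 20 rises of NSBP1SE set beside the 18S signal above. By the same choice the empty vector mean of each lay below NSBP1WT and NSBP1SE. It also lay below NSBP1 siRNA and control siRNA (for Canx 10.2, where the 4 other groups lay between 10.8 and 11.2). Of the falls, the empty vector mean lay above all other groups for Aox3, Sema5a, Slc1a2 and Stbd1. For Mmp16, Purg, Tenm3 and Tln2 it lay within the range of the other groups. A single gene, Dmkn, went in opposite directions (0.36 and -0.45). Across genes the effects had a Pearson r of 0.164 and a Spearman rho of 0.160. The simulated correlation holds for unchanged groups, and changes in a single group lower it, so it is no reference for these values. The covariance was 0.00576 against a simulated 0.00479, a difference of 0.000972. With the empty vector arrays split between the comparisons, r ranged from -0.0679 to 0.166 over 6 splits. The number of shared changes was 5 without NSBP1WT replicate 1 or 3, 4 without NSBP1WT replicate 2, 1 without empty vector replicate 2 or 3, 43 without NSBP1SE replicate 1 and 1 without NSBP1SE replicate 2 or 3. Dmkn lost its call in at least 1 comparison without any NSBP1WT array, without empty vector replicate 2 or 3 and without NSBP1SE replicate 2 or 3, which left 0 genes with opposite changes.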

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

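Of the tests below, those of ribosomal RNA and of whole-gene rises in NSBP1SE, of a labelling batch, of a dose effect, and the fits with the actin or 18S covariate were chosen only after the result was seen.

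The effects of NSBP1WT and NSBP1SE, each set against empty vector, differed in 2988 genes by the test of the difference itself, which is the direct comparison of both groups described above. The control probe sets, outside the gene tests, held signals above those of the empty vector arrays. The mean 18S signal was 8.66 ± 1.81 (SD, n = 3) in NSBP1SE and 5.84 ± 0.42 (SD, n = 3) in empty vector. The 5′ signal of the Thr spike was 7.94 ± 0.40 (SD, n = 3) in NSBP1WT and 5.53 ± 0.39 (SD, n = 3) in empty vector, and at most 6.43 in the 12 arrays of other groups.

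The 20 rises in NSBP1SE, led by Rpl27a, were larger where the 18S signal was high, with a median of 0.59 in replicate 1 and 1.09 in replicates 2 and 3, while the 25 falls had medians of -0.51 and -0.59. A rise of all transcripts of these genes with the mutant protein would also raise their other probe sets, where these detect the transcript. The median change of 28 other probe sets was -0.0791 (standard error 0.130) where the sets used gave 0.88. The other probe sets are by choice those of lower mean level, and whether they detect the transcripts was not measured, so that rise is not excluded. In the other 12 arrays, the within-group deviations of the 20 genes followed those of the 18S signal with a median r of 0.739, where the middle 95% of 1000 random gene sets lay between -0.340 and 0.0639. The random sets were matched on mean level only. Sets of genes that vary together would spread more widely, so that range is a loose reference. The 18S signal varied most among the control siRNA arrays (SD 0.81, n = 3). The SD was 0.42 in empty vector, 0.29 in NSBP1WT and 0.08 in NSBP1 siRNA. No array was left out in turn from this test. Labelled RNA rich in ribosomal RNA is a candidate explanation of these rises. In replicate 1 the 18S signal was 6.58, within the 5.36 to 7.21 of the 12 arrays of other groups. It lay above the 3 empty vector arrays (6.15, 5.36 and 6.01) with which the rises were compared. Whether the 18S signal accounts for the rises in replicate 1 therefore stays open. The explanation stays a hypothesis for the other replicates too, since the genes were chosen in a comparison with the empty vector arrays, 3 of these 12, and a change of single transcript forms in NSBP1SE was not tested.

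The NSBP1WT arrays stood apart in their labelling controls as well as in their genes, with Thr spike 3′ to 5′ differences 0.981 below the lowest of the other 12 arrays. A separate labelling batch of these arrays cannot be told apart from the effect of the protein, because the gap coincides with the group. For a loss of RNA 5′ ends, the change from replicate 3 to replicate 1 ran along the group's change (r = 0.351 across genes past the test), as that loss would give, but a stronger effect in replicate 1 for any other reason would give it too. The actin control stood apart in these arrays, while the Gapdh control lay within the range of the other 12 arrays. The actin difference was larger than in the other arrays, where that of the Thr spike was smaller. A dose effect of NSBP1 would turn signs between siRNA and NSBP1WT, and among these genes r was -0.184 with 59.4% of opposite sign, which leaves it open because Hmgn5 did not measure the dose in the clones. With the actin covariate 12 genes passed. The median standard error rose from 0.107 to 0.212, and the median absolute effect of the 2354 genes, which were chosen by the fit without it, went from 0.435 to 0.340 (r = 0.896 between both sets of effects), so the lost calls went with larger standard errors and with smaller effects. The hypoxia median was 0.41 beside 0.44 without the covariate and the mitosis median -0.27 beside -0.20, and both lists still passed. The calls ended for ribosome biogenesis (-0.038 beside -0.137, adjusted p = 0.113), ribosomal proteins (-0.061 beside -0.063, 0.304) and HMG genes (-0.129 beside -0.142, 0.272).

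Replicates 1 and 3 of NSBP1 siRNA differed more than any replicate pair of the other 4 groups, with an SD across genes of 0.435 where those pairs lay between 0.147 and 0.226. Replicate 1 also had the narrowest signal range, an interquartile range of 3.12 where the other 14 arrays lay between 3.29 and 3.70. A compressed range as the whole cause was excluded, since quantile normalization lowered that SD by 2.51%. After quantile normalization, the difference between replicates 1 and 3 ran along the effect seen in replicate 2 (r = 0.523 across genes), as a stronger siRNA effect in replicate 1 predicts. Hmgn5 was lowest there (5.53, beside 6.11 and 6.31), so unequal silencing is a candidate explanation, which 3 arrays cannot settle.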

How the results depend on the processing

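The fits with the actin or 18S covariate, with replicate 1 as the sole NSBP1SE array, on the 9 clone arrays alone and with gene-by-gene array weights were chosen only after the result was seen. Of 439 results for named genes, 349 passed the test, 338 of these kept their direction under all alternatives run, and 253 of the 349 also passed in every fit that left out an array. No cause was tested for the changes below, except where a setting tests fewer genes, uses fewer arrays or applies a stricter threshold. Signal over background was not measured apart from the level, and the filter at the median level is the alternative that bears on it.

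The results are given in the order siRNA, NSBP1WT, NSBP1SE, NSBP1WT against NSBP1SE, and the difference between the siRNA and NSBP1WT effects, and the counts for all values as deposited were 3464, 2354, 45, 2988 and 3078. Array weights gave 8614, 5052, 449, 5230 and 7491, but their estimation stopped before it converged and put a weight of 248 on NSBP1 siRNA replicate 2. Gene-by-gene weights gave 6154, 4662, 355, 4910 and 5861. The actin covariate gave 1668, 12, 15, 56 and 66. With each of the 45037 probe sets other than controls tested on its own, 5878, 4420, 5180 and 4757 probe sets passed, NSBP1SE aside. These count probe sets, where the other counts are of the 18193 genes. A 1.5-fold minimum gave 939, 495, 698 and 1732, again without NSBP1SE, and an adjusted p under 0.01 gave 1304, 1092, 1, 1511 and 1484. The arrays of the compared groups alone gave 468, 3981 and 72 for the first 3. Fewer arrays do not by themselves account for the larger counts of 3981 and 72. These fits also do not share a spread with the other groups. The 9 clone arrays gave 3915, 190 and 4684 for NSBP1WT, NSBP1SE and their comparison. The 18S covariate gave 0 for NSBP1SE by limma (318 at an unadjusted p under 0.05) and 809 for NSBP1WT against NSBP1SE. With replicate 1 as the sole NSBP1SE array, taken to vary like the other groups, these were 0 (428 at an unadjusted p under 0.05) and 549. For NSBP1SE alone, quantile normalization gave 23, the level filter 78, the mean of probe sets 18 and the intensity trend 112.

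Leaving out arrays in turn gave 1912 to 6531 genes for siRNA, 1339 to 1751 for NSBP1WT, 1 to 101 for NSBP1SE, 1826 to 2389 for NSBP1WT against NSBP1SE and 2111 to 5484 for the difference. The Hmgn5 change ranged from -3.66 to -3.27, from -0.58 to -0.47, from -0.05 to 0.04 and from -0.58 to -0.46 in the 4 comparisons. Opposite changes under siRNA and NSBP1WT ranged from 195 to 767, equal ones from 83 to 410, and their correlation from -0.0646 to 0.0133. Shared changes of NSBP1WT and NSBP1SE ranged from 1 to 43, opposite ones from 0 to 1, and their correlation from 0.116 to 0.235. Lists past the test ranged from 4 to 6, 8 to 10, 4 to 8 and 8 to 9.

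Quantile normalization moved the genes changed alike under siRNA and NSBP1WT from 176 to 294 and their correlation to -0.0768, and the level filter moved these to 268 and -0.133. For NSBP1WT and NSBP1SE, shared changes moved from 15 to 9 with quantile normalization, to 25 with the level filter and to 0 with replicate 1 as the sole NSBP1SE array. Opposite changes were 0 with quantile normalization, with centring on medians and with replicate 1 as the sole NSBP1SE array, and 4 with the level filter. Their correlation was 0.107 with replicate 1 as the sole NSBP1SE array, and -0.0679, 0.0309, 0.0862 and -0.0112 in the 4 splits of the empty vector arrays that moved it most. With an estimated correlation, 0 lists passed in each comparison. The number of lists past the test moved for siRNA from 7 to 4 with quantile normalization and to 3 with the level filter, which ended 4 and 6 of the 7 calls. For NSBP1SE it moved from 5 to 2 with the level filter, to 2 with the 18S covariate and to 3 with replicate 1 as the sole NSBP1SE array.

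With the mean of all probe sets, the sign turned for Tyms (0.0212), Kif23 (-0.0227) and Gh (0.53, adjusted p = 0.0254) under siRNA, for Syt4 (0.0138), Snap25 (0.00227), Slc7a1 (-0.10), Atp5a1 (0.10) and Ncam1 (-0.0516) in NSBP1WT, and for Syt4 (0.0535) and Slc7a1 (-0.0724) in NSBP1WT against NSBP1SE. With the actin covariate it turned for Eif4e (0.0548) in NSBP1WT and Hmgb3 (0.0160) in NSBP1WT against NSBP1SE.

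The replicate numbers did not pair the arrays. Of 30 pairs with the same number in different groups, 2 had correlated deviations above 0.1 (from -0.263 to 0.197), and 2 of 15 arrays correlated best with their own number, a hint from the data and not the design. With a replicate block the counts were 3141, 2083, 6, 2674 and 2752, with 4 shared and 0 opposite changes of NSBP1WT and NSBP1SE.

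For each comparison of 3 arrays with 3 there were 10 splits, too few for a share under 0.05. The real split was the 1 with most genes, at 3464 where the highest other gave 65 for siRNA, and at 2354, 45 and 2988 where the highest other gave 0 by limma for the other comparisons. For lists, 2 splits reached the real 7 under siRNA (highest other 8), 2 the 9 in NSBP1WT (10), 4 the 5 in NSBP1SE (6) and 3 the 8 in NSBP1WT against NSBP1SE (9). Among 100 drawn splits, 1, the real one, gave as many genes for the difference of effects (3078, highest other 1122), for opposite changes under siRNA and NSBP1WT (399, highest other 4) and for shared changes of NSBP1WT and NSBP1SE (15, highest other 1). For the first of these counts this speaks against groups that do not differ at all. It cannot tell an effect of NSBP1 from a batch or clone difference that coincides with a group. Wrong splits mix unlike groups, which widens the spread within them. The wrong splits gave few calls or 0 in each comparison by itself, so the last 2 counts say nothing about opposite or shared changes beyond those calls.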

Other observations

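The test of this part was written down before its result was seen, and leaving out arrays from it was added after. Nhlh2, the largest rise under siRNA, is a neuronal helix-loop-helix factor of hypothalamic and neuroendocrine cells. Its level, with its spread, was 7.48 ± 0.21 (SD, n = 3) with NSBP1 siRNA, 6.45 ± 0.22 in NSBP1WT, 7.54 ± 0.21 in NSBP1SE and 7.02 ± 0.13 in empty vector, but 4.59 ± 0.18 with control siRNA. Its level with control siRNA was thus below that of the 4 other groups, and the size of the rise rests on the control siRNA arrays.

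Glycolysis and hypoxia genes also varied between cultures of the same group. Relative to the mean of all arrays, the mean of the list was 0.25, 0.46 and -0.11 in the control siRNA arrays and -0.35, -0.06 and -0.07 in the empty vector arrays, beside 0.42, 0.35 and 0.38 in NSBP1WT and -0.38, -0.37 and -0.48 in NSBP1SE. A hypothesis was that the other NSBP1WT changes follow how genes vary with this list between cultures. The test left it open. Across 2338 genes outside the list, the NSBP1WT effect and each gene's covariance with the list in the 6 control siRNA and NSBP1SE arrays had r = 0.0516, but leaving out arrays in turn gave values from -0.246 to 0.178. The list varied by 0.567 among the control siRNA arrays and by 0.110 among the NSBP1SE arrays, so the covariance rests mostly on 3 arrays.

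Under siRNA the median change depended on the expression level. It was 0.03, 0.11, 0.14, 0.13 and 0.02 in the 5 lower of 10 equal bins of genes by mean level, and -0.12, -0.15, -0.12, -0.08 and -0.03 in the 5 upper bins.

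The 3′ to 5′ difference of the Thr spike was 0.65 ± 0.07 (SD, n = 3) in NSBP1WT, where the other 12 arrays lay between 1.70 and 2.90. For the Dap spike it was 0.73 ± 0.18 (SD, n = 3) in NSBP1WT, where the other 12 arrays lay between 1.49 and 1.97.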
